A study of Mus musculus with 9 samples.

How the data were processed

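Liver RNA of C57Bl6 mice was measured by RNA sequencing in 9 libraries of 3 groups, with 3 libraries per group: untreated mice of 2 months (young), untreated mice of 20 to 22 months (aged), and mice of 20 to 22 months given PD-0332991 in chow for 2 weeks. The group and replicate number of each library were taken from the labels. The labels give the amount of drug in the chow as 450 with the unit written mg/k. Per the labels' protocols, total RNA was made into paired-end libraries with an Illumina TruSeq RNA kit; strand is not stated. Per the submitters' processing notes, transcript abundance was estimated with kallisto and the build is mm10. The kallisto version, the transcript annotation and the step from transcripts to genes are not given in the sources used here.

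The authors deposited 1 table per library with a gene symbol and a TPM value, a relative transcript abundance, on each of 23444 rows, and the same symbols in all 9 files. TPM divides out transcript length and library size, so it keeps no sequencing depth: the depth of each library is unknown, and no counting intervals are given. The listed TPM values summed to between 53.1% and 57.6% of the full TPM scale per library, so the tables hold part of what was quantified. In all 9 libraries Alb, the albumin gene of hepatocytes, was listed at 0, and no mitochondrial genes or immunoglobulin and T cell receptor constant genes were listed. A value of 0 is therefore read here only as listed at 0. In the tables, 6604 genes were at 0 in all libraries. Symbols that a spreadsheet had turned into dates were kept where they occurred once (23 rows) and left out where a date stood for more than 1 gene (4 rows). Some symbols are older ones, such as Ccrn4l for the gene now called Noct.

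Values were compared on the log2(TPM + 0.5) scale, which understates the change of low genes. Genes with a TPM of 1 or more in at least 3 libraries were tested (10161 genes). All 9 libraries were fitted in a single model with the group as the only term, using limma 3.58.1 in R 4.3.3 with an intensity trend and robust variance estimation, and the contrasts aged against young, PD-0332991 against aged, and PD-0332991 against young were tested two-sided. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called changed. The count-based test planned for tables of counts was not applicable to TPM; the test used was the one planned for normalized values. The labels do not say whether the 3 libraries of a group came from separate mice, so the p-values measure the spread between these libraries. No 2 libraries held identical values.

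In total 40 gene lists (pathways, cell type markers, tissue checks) with 979 members were fixed before the data were examined. Of the members, 952 were found by symbol and 11 by an older synonym, and 16 were not listed. The 34 lists with at least 5 tested members were tested with limma's camera at its preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over the lists of a comparison. Each was tested again with an estimated correlation, and with fry. With the estimated correlation no list passed in any of the 3 comparisons. The number of members called is given over all genes tested and also adjusted over the list alone.

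The genes named were chosen by a rule fixed before the data were examined. The rule took, for the age and the drug comparison, the 10 genes with the largest rise and the 10 with the largest fall among called genes with a mean of 5 TPM or more in the higher group and no overlap between the groups. For treated against young livers it took 5 and 5. Predicted and clone-named genes were left out. The rule added up to 4 called members and up to 2 members not past the threshold of each gene list, and in every case Cdk4, Cdk6, Ccnd1, Cebpa, Cebpb, Ep300, Hdac1, Dgat1, Dgat2, Plin2, Cdkn1a, Cdkn2a and Mki67. Other genes are named only where the text says that they were chosen after their values were seen. The result of 1 gene that the rule names is not reported here.

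The relation of the age and drug effects was measured over genes by Pearson's r, Spearman's rho and the covariance. Both effects use the aged untreated libraries, so draws with no change in any group were simulated. For the correlations and the covariance, 1000 draws rotated the residuals of the fit at random, which keeps the correlation between genes. For the overlap of calls, 100 draws used the fitted variances, with each gene drawn independently. These were drawn on the log scale in place of the planned simulation of counts. Single values per library were compared by exact two-sided permutation tests, which for 3 against 3 libraries cannot give a p below 0.1. The limma and camera steps were tested on simulated data made from the real means and variances with 200 of 10161 genes changed. For the drug comparison, of the changed genes 36.4% were recovered at an absolute log2 fold change of 0.5 (66 genes), 92.5% at 1 (67 genes) and 100% at 2 (67 genes), and 8.93% of calls were false. For the age comparison the recovered shares were 33.3%, 94.0% and 98.5%, with 6.79% false, and for treated against young livers 21.2%, 88.1% and 97.0%, with 8.61% false. None of 20 unchanged lists was called in the age comparison. The genes were drawn independently, so this does not test camera at the preset correlation where genes of a list vary together.

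Alternatives tried were the pseudocount, the filter, the threshold, a fit of the 6 compared libraries alone, the replicate number as a block, leaving out each library, other scalings between libraries, weights per library, other set tests and, for the relation of the effects, a division of the aged untreated libraries. A fit that left out 2 libraries chosen by their Saa1 values was also run and is not used, because it selects libraries by a measured outcome. Gene positions are from the GENCODE annotation of GRCm38 (mm10), 1-based, matched by symbol. Genes with near-identical copies, whose reads the quantification could split (Cyp2c40 and Cyp2c69, Gstp1 and Gstp2, Saa1 and Saa2, C4a, H2-K2, Ifi27l2a and Ifi27l2b), are uncertain. The same holds for genes that overlap a gene on the opposite strand (Cdk4 with Tspan31, Junb with Prdx2, Cebpb with Tmem189, Tifa with Ap1ar, Irf1 with Gm17334, Ctcflos with Ctcfl). Tables were handled with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and drawn with matplotlib 3.10.9.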

Results

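Gene expression was measured in the livers of young untreated mice (2 months), aged untreated mice (20 to 22 months) and aged mice fed chow with PD-0332991 for 2 weeks, with 3 libraries per group. PD-0332991, also called palbociclib, is an inhibitor of the cell cycle kinases CDK4 and CDK6, and the title of the series names Cdk4 and fat accumulation in the ageing liver. The deposited values are TPM, so the depth behind them is unknown. A TPM of 1 was reached by 9930 ± 99.6 genes in young, 9843 ± 42.8 in aged untreated and 9585 ± 36.7 in treated libraries (mean ± SD), and all 3 treated libraries (9543 to 9611) lay below all 6 untreated ones (9794 to 9989). Young libraries lay above the others in the genes above 0 TPM (15077 against 14505 aged untreated and 14420 treated) and in the share of the listed TPM held by the top 10 genes (21.9% against 19.8% and 19.1%). Each of these differences without overlap had an exact permutation p of 0.1, the smallest that 3 against 3 libraries allow (adjusted p = 0.25 over 15 tests). Over genes, libraries of the same group correlated with Pearson's r from 0.970 to 0.990 (9 pairs) and libraries of different groups with r from 0.964 to 0.982 (27 pairs). The first principal component held 35.6% of the variance and placed young livers between -23.8 and -16.2 and treated livers between 16.1 and 29.5. Aged untreated replicates 1, 2 and 3 lay at 12.4, -2.49 and -13.3 on it. The Y-linked gene Ddx3y was at 5.83 to 8.48 TPM in all 9 libraries and Xist, which silences an X chromosome in females, at 0.0125 TPM or below.

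The first comparison asked how the untreated liver differs between 20 to 22 months and 2 months. Serpine2, a secreted inhibitor of serine proteases (chromosome 1, 79794197 to 79861180), rose from 3.09 ± 0.441 TPM in young to 15.9 ± 3.04 TPM in aged livers (mean ± SD, n = 3 libraries per group here and below), a log2 fold change of 2.18 ± 0.17 (SE; limma, adjusted p = 0.000355). Susd4, which encodes a regulator of complement (chromosome 1, 182763860 to 182896591), rose from 3.11 ± 0.573 to 9.58 ± 0.764 TPM (log2 fold change 1.49 ± 0.14, limma adjusted p = 0.0013). Lifr, the receptor of leukemia inhibitory factor (chromosome 15, 7090614 to 7197489), fell from 101 ± 12 to 49.5 ± 8.53 TPM (log2 fold change -1.02 ± 0.13, limma adjusted p = 0.00689). Hhex, a homeobox transcription factor of liver development (chromosome 19, 37434810 to 37440731), fell from 89.5 ± 15.3 to 37.9 ± 8.29 TPM (log2 fold change -1.23 ± 0.23, limma adjusted p = 0.0362). In all, 112 of 10161 genes were called, 66 higher and 46 lower in aged livers, and 47 of them changed by at least 1 on the log2 scale. An unadjusted p under 0.05 was reached by 1523 genes, where chance alone gives 508 on average, and 18.4% of genes had no overlap between the groups, where chance gives 10%. Genes vary together, and the highest other split of the 6 libraries into 3 and 3 reached 1434 genes. Such splits, here and below, mix the real groups, which can lower their counts. The count was 16, 38 and 50 without young replicate 1, 2 or 3, and 40, 64 and 696 without aged replicate 1, 2 or 3.

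Among called genes of 5 TPM or more in the higher group, predicted and clone-named genes aside, others with the largest rises were Ifi27l2b (log2 fold change 2.43), Serpinb1a, an inhibitor of neutrophil proteases (2.41), Ccrn4l, the clock-controlled gene now called Noct (2.34), and Acnat2 (2.27). They were followed by the glutathione transferase gene Gstp2 (1.75), Nat8 (1.71), the cytochrome P450 gene Cyp2b10 (1.60) and Dnajb9, a co-chaperone of the endoplasmic reticulum (1.47). Under the same limits the largest falls, beside those of Hhex and Lifr, were those of Cyp2c40 (-1.74), Gbp11 (-1.64), Hykk (-1.19), the collagen gene Col3a1 (-1.17), Wsb1 (-0.99), the coagulation factor gene F11 (-0.95), Vgll4 (-0.94) and Grpel2 (-0.94). All of these passed the limma threshold, with adjusted p from 0.00451 for Serpinb1a to 0.0447 for Acnat2 among the rises and from 0.00798 for Hykk to 0.05 for F11 (rounded) among the falls. Of the 42 named genes called with age, 6 stayed past the threshold without any 1 library: Serpine2, Susd4, Lifr, Ifi27l2b, Serpinb1a and Cyp2c37. The other 36 kept their direction but were no longer called in at least 1 such fit, 34 of them without young replicate 1, 26 without young replicate 2, 22 without young replicate 3, 23 without aged replicate 1 and 18 without aged replicate 2. Their adjusted p then lay between 0.0514 and 0.195.

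**Figure D1:**
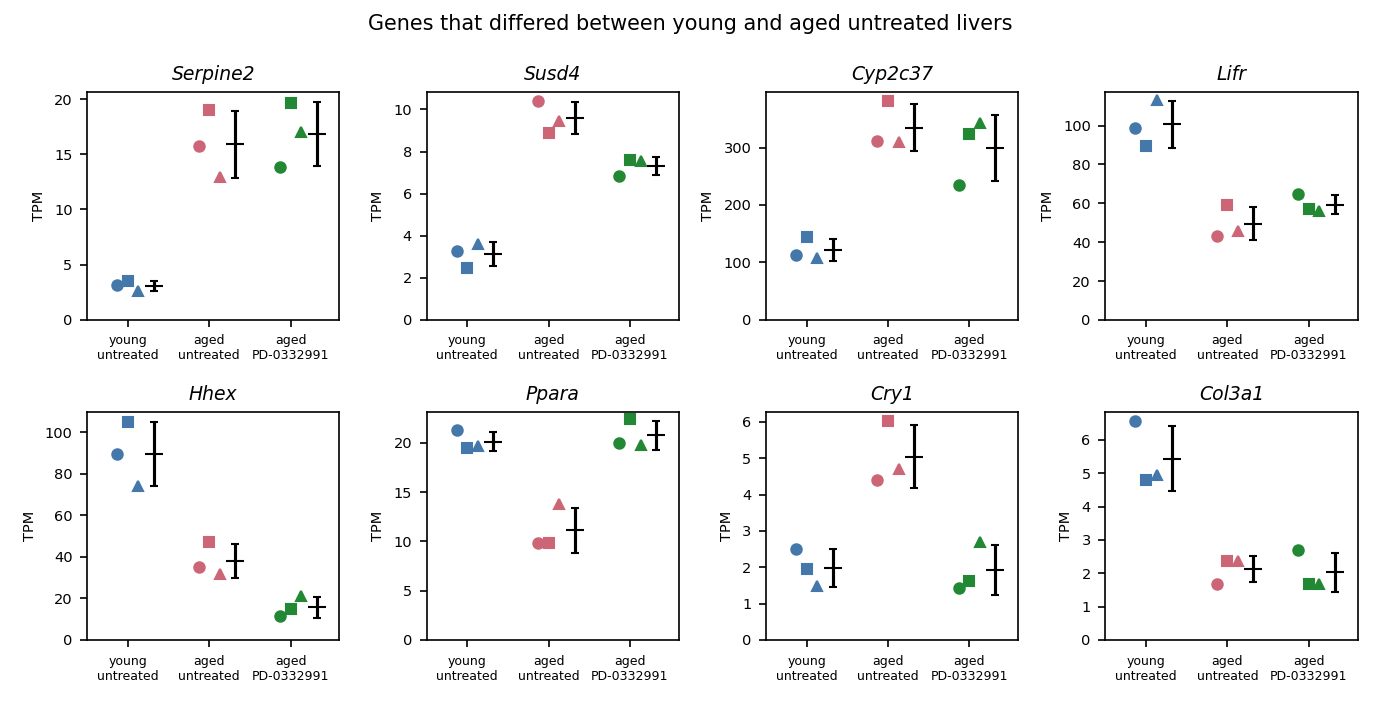
TPM of 8 genes in each library (circle, square and triangle for replicates 1, 2 and 3) by group, with the mean and SD beside the points. Serpine2 averaged 3.09 TPM in young and 15.9 TPM in aged livers, and Lifr 101 and 49.5 TPM.

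Genes of xenobiotic metabolism were higher in aged livers. Of 29 tested members 3 rose and none fell (5 and 1 adjusted over the list alone), with a median log2 fold change of 0.22 (camera adjusted p = 7.08e-05; adjusted p = 0.505 with an estimated correlation). The median was 0.12 without young replicate 2, 0.36 without aged replicate 1, 0.14 without aged replicate 2, 0.14 with quantile normalization and 0.10 with array weights. Cyp2c37 rose from 122 ± 19.4 to 334 ± 41.1 TPM (limma adjusted p = 0.00407), and Cyp2b10 and Gsta2 were the others. Periportal genes, expressed around the portal vein, had 2 of 20 members higher and none lower (4 and 1 adjusted over the list alone; camera adjusted p = 0.00909, and adjusted p = 0.505 with an estimated correlation). These were Igfbp2, an insulin-like growth factor binding protein (321 ± 18.3 to 576 ± 24.9 TPM), and Pigr, the transporter of polymeric immunoglobulin (183 ± 21.1 to 293 ± 10.8 TPM). Pericentral genes had 1 of 17 members higher, the glutamate transporter gene Slc1a2, and 4 adjusted over the list alone (camera adjusted p = 0.0215; adjusted p = 0.505 with an estimated correlation). Without aged replicate 3 the camera adjusted p was 0.108 for the periportal and 0.0803 for the pericentral list. The pericentral call was also lost with no filter (0.0668) and with quantile normalization (0.0751), and its median of 0.17 was 0.28 without aged replicate 1, 0.28 without aged replicate 3, 0.11 with no filter and 0.31 with genes of 5 TPM or more in at least 3 libraries. The periportal median of 0.10 was 0.19 without young replicate 2, 0.16 without aged replicate 2 and 0.04 without aged replicate 3.

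Genes of the interferon response were lower in aged livers. Of 32 tested members 3 fell and none rose (5 and 0 adjusted over the list alone), with a median log2 fold change of -0.37 (camera adjusted p = 4.31e-06; adjusted p = 0.505 with an estimated correlation). With genes of 5 TPM or more in at least 3 libraries the interferon median was -0.19. The guanylate-binding protein gene Gbp6 had a log2 fold change of -1.09 (limma adjusted p = 0.0278), the chemokine gene Cxcl9 of -1.01 (0.033) and Usp18, which fell from 4.04 ± 0.371 to 2.12 ± 0.469 TPM, of -0.81 (0.0496). Class II antigen presentation genes were lower as a list (median -0.40 over 7 members, none called and 0 adjusted over the list alone; camera adjusted p = 0.011, and adjusted p = 0.571 with an estimated correlation). That call was lost without young replicate 3 (adjusted p = 0.0664) or aged replicate 2 (0.121, with a median of -0.17), and the median was -0.23 with no filter. Stellate cell and extracellular matrix genes had 2 of 26 members lower, Col3a1 (5.44 ± 0.978 to 2.13 ± 0.389 TPM) and Sparc (21.6 ± 1.69 to 13.4 ± 1.72 TPM), and 5 lower and 1 higher adjusted over the list alone. The median of that list was -0.21 (camera adjusted p = 0.000545; adjusted p = 0.607 with an estimated correlation). It was -0.32 without aged replicate 2, and the call was lost with genes of 5 TPM or more in at least 3 libraries (0.102).

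Genes of fatty acid oxidation and targets of PPAR-alpha were lower with age as a list (median -0.23, 31 members, camera adjusted p = 1.09e-05; adjusted p = 0.505 with an estimated correlation). Only Ppara itself, the nuclear receptor of the pathway, passed over all genes tested, falling from 20.1 ± 0.989 to 11.1 ± 2.29 TPM (limma adjusted p = 0.0144), and 6 members were lower adjusted over the list alone. Angptl4 (70.0 ± 16.8 and 39.0 ± 6.38 TPM, adjusted p = 0.0621) did not pass. Genes of de novo lipogenesis had no called member over all genes, 1 lower adjusted over the list alone and a median of -0.25 (camera adjusted p = 0.0276; adjusted p = 0.878 with an estimated correlation). This call was lost without young replicate 1 (0.136) or 3 (0.152) and without aged replicate 2 (0.0557) or 3 (0.0598), and with no filter (0.0813), and the median was -0.40 without young replicate 2. Triglyceride synthesis and lipid droplet genes did not pass as a list (camera adjusted p = 0.898), and Plin2 was at 304 ± 17.5 TPM in young and 209 ± 42.6 TPM in aged livers (adjusted p = 0.102). Male-biased liver genes were lower (median -0.23, 24 members, camera adjusted p = 0.00912; adjusted p = 0.607 with an estimated correlation), with Keg1 lower, Susd4 higher, and 7 lower and 2 higher adjusted over the list alone. Without young replicate 3 that list had an adjusted p of 0.282 and a median of -0.11. Genes of the insulin and growth hormone axis were also lower as a list (median -0.24, 14 members, camera adjusted p = 0.0234; adjusted p = 0.475 with an estimated correlation), with Lifr lower and Igfbp2 higher, and 2 lower and 1 higher adjusted over the list alone. That call was lost without young replicate 2 (0.0753) or aged replicate 3 (0.296), and with no filter (0.0668).

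Acute phase genes, which the liver secretes during inflammation, were higher in aged livers as a list but very uneven between libraries. The median log2 fold change of the 28 members was 0.57 and 27 lay above 0 (camera adjusted p = 4.6e-07; adjusted p = 0.583 with an estimated correlation), while no member passed alone, over all genes tested or adjusted over the list alone. The acute phase median was 0.24 without aged replicate 1 and 0.88 without aged replicate 3 or with array weights. Saa1 read 6008, 222 and 123 TPM in aged replicates 1, 2 and 3 and 38.3, 1482 and 52.3 TPM in young replicates 1, 2 and 3. This gene, like Lcn2, Mt1, Mt2, Dbp and Nr1d1, was picked after its values were seen. Neutrophil genes were higher as a list (median 1.43 over the 5 tested of 15 listed members, camera adjusted p = 4.69e-05, and adjusted p = 0.475 with an estimated correlation). None was called over all genes, and 5 were higher adjusted over the list alone. The neutrophil median was 0.94 without aged replicate 1 and 0.41 with no filter. S100a9 was at 1.55 ± 0.515 TPM in young and 6.94 ± 4.77 TPM in aged livers. Immediate early and heat shock genes had a median of 0.29 over 18 members, with none called and 1 higher adjusted over the list alone (camera adjusted p = 0.0276; adjusted p = 0.475 with an estimated correlation). Without young replicate 3, aged replicate 1 or aged replicate 2 the adjusted p of that list was 0.164, 0.112 or 0.0517, and with genes of 5 TPM or more in at least 3 libraries it was 0.0768.

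The second comparison asked what PD-0332991 changed in the aged liver. Cxcl1, a chemokine that attracts neutrophils (chromosome 5, 90891241 to 90893115), rose from 16.1 ± 10.8 to 165 ± 19.5 TPM, a log2 fold change of 3.52 ± 0.42 (limma adjusted p = 0.0158). Angptl4, a secreted inhibitor of lipoprotein lipase (chromosome 17, 33773750 to 33781830), rose from 39.0 ± 6.38 to 121 ± 13.1 TPM (log2 fold change 1.63 ± 0.18, limma adjusted p = 0.00961), and Plin2, a coat protein of lipid droplets (chromosome 4, 86648386 to 86670060), from 209 ± 42.6 to 417 ± 64.1 TPM (limma adjusted p = 0.0156). Slc40a1, the iron exporter ferroportin (chromosome 1, 45908068 to 45926523), fell from 21.7 ± 2.27 to 10.4 ± 0.722 TPM (log2 fold change -1.02 ± 0.13, limma adjusted p = 0.0116), and Hhex fell from 37.9 ± 8.29 to 15.7 ± 4.97 TPM (-1.27 ± 0.23, 0.0259). In all, 147 genes were called, 62 higher and 85 lower with the drug, and 41 of them changed by at least 1 on the log2 scale. With median-of-ratios scaling the split was 109 higher and 56 lower, and with quantile normalization 88 and 56. An unadjusted p under 0.05 was reached by 1854 genes (508 by chance on average, 965 in the highest other split), and 22.4% of genes had no overlap between the groups (10% by chance). The count was 240, 40 and 392 without aged untreated replicate 1, 2 or 3, and 85, 7 and 12 without treated replicate 1, 2 or 3.

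Under the same limits as with age, other genes with the largest rises were Junb, a subunit of the AP-1 transcription factor (log2 fold change 1.97), Fbf1 (1.75), Ctcflos (1.58), the thyroxine-binding globulin gene Serpina7 (1.58) and the interferon regulatory factor Irf1 (1.23). H2-K2 (1.18), the mitochondrial carrier gene Slc25a47 (1.16) and the autophagy gene Atg14 (1.09) completed these. Also under these limits, the largest falls beside those of Hhex and Slc40a1 were those of the clock repressor Cry1 (-1.23), the vasopressin receptor gene Avpr1a (-1.07), the transcription factor Gata4 (-1.05), the sphingosine-1-phosphate receptor gene S1pr1 and Sh3bp2 (-0.98). The integrin gene Itga5, Adam11 and Shf each had a log2 fold change of -0.97. All passed the limma threshold, with adjusted p from 0.00961 for Atg14 to 0.0259 for Hhex. Of the 40 named genes called with the drug, Angptl4, Atg14 and Slc40a1 stayed past the threshold without any 1 library. The other 37 kept their direction but were no longer called in at least 1 such fit: 35 without treated replicate 2, 32 without treated replicate 3, 27 without aged untreated replicate 2, 18 without treated replicate 1, 2 without aged untreated replicate 1 and 1 without aged untreated replicate 3. Their adjusted p then lay between 0.0512 and 0.158.

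**Figure D2:**
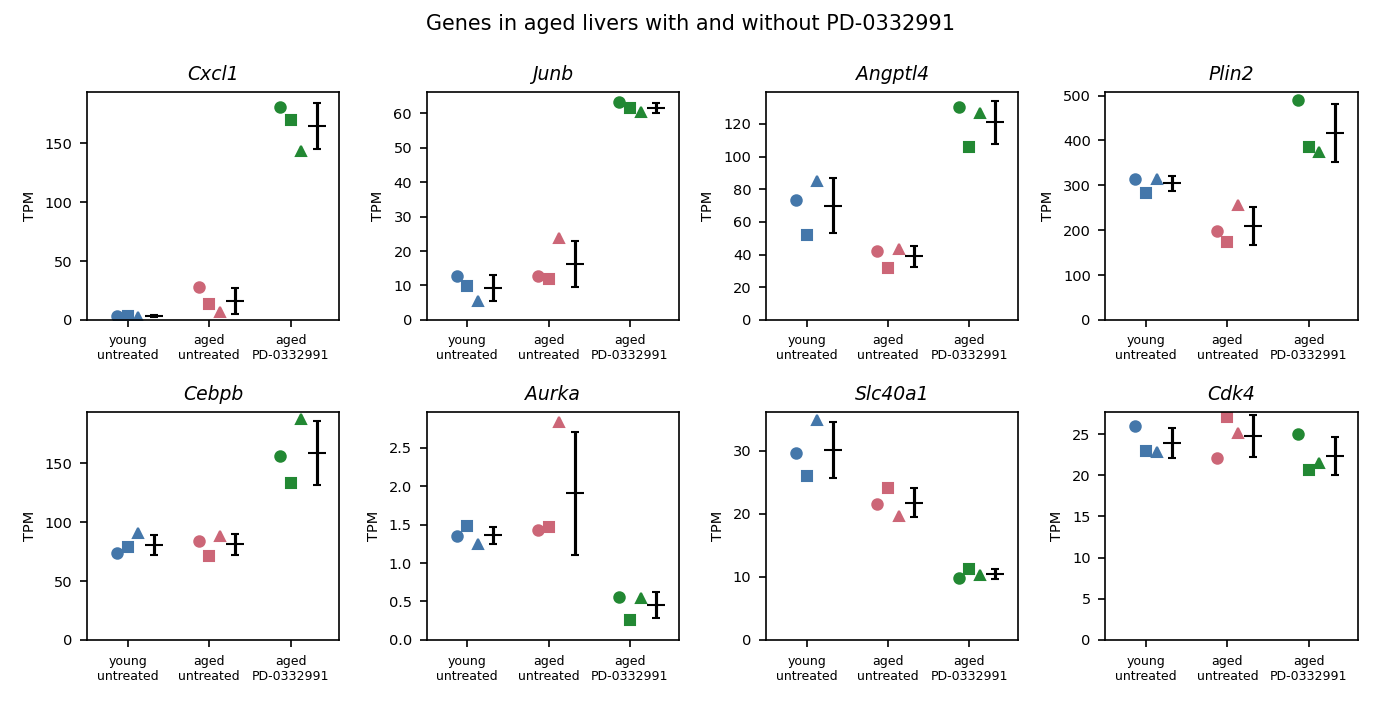
TPM of 8 genes in each library (circle, square and triangle for replicates 1, 2 and 3) by group, with the mean and SD beside the points. Plin2 averaged 209 TPM in aged untreated and 417 TPM in aged treated livers, while Cdk4 averaged 24.7 and 22.4 TPM.

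Cell cycle genes and targets of E2F, the transcription factors held back by RB when CDK4 and CDK6 are inactive, were lower in treated livers. Of 21 tested members 20 lay below 0, with a median log2 fold change of -0.69 (camera adjusted p = 3.62e-06; adjusted p = 0.50 with an estimated correlation). Over all genes 2 passed, and 12 were lower adjusted over the list alone. Aurka, a mitotic kinase (chromosome 2, 172356190 to 172370535), fell from 1.91 ± 0.798 to 0.459 ± 0.169 TPM (limma adjusted p = 0.0215), and the replication helicase gene Mcm6 from 2.56 ± 1.38 to 0.616 ± 0.106 TPM (0.0489). The call of Aurka was lost without treated replicate 2 (0.0971) or 3 (0.0723), and that of Mcm6 without aged untreated replicate 2 (0.114) or 3 (0.0521) or treated replicate 1 (0.11), 2 (0.135) or 3 (0.156). The levels were low, and with genes of 5 TPM or more in at least 3 libraries the list did not pass (adjusted p = 0.115, median -0.22). Mki67, a marker of dividing cells, was below 1 TPM in all 9 libraries and was not tested: it read 0.0654, 0.623 and 0.516 TPM in aged untreated and 0.0821, 0.0432 and 0.0435 TPM in treated replicates 1 to 3. Cdk4 (chromosome 10, 127063534 to 127067920) was at 24.7 ± 2.51 TPM in untreated and 22.4 ± 2.33 TPM in treated aged livers (log2 fold change -0.14 ± 0.11, adjusted p = 0.539), and at 23.9 ± 1.79 TPM in young livers. Cdk6 was listed between 0.512 and 1.07 TPM and Cdkn2a between 0 and 0.725 TPM over the 9 libraries, and neither was tested. The list of CDK4/6 and RB pathway genes did not pass (median -0.24, 13 members, camera adjusted p = 0.0581). In it Cdkn2c, which encodes an inhibitor of CDK4 and CDK6, fell from 1.96 ± 0.203 to 0.801 ± 0.315 TPM (limma adjusted p = 0.0259), and 2 members were lower adjusted over the list alone. Cdkn1a was at 1.48 ± 0.47 TPM in young, 8.79 ± 4.51 TPM in aged and 2.45 ± 1.06 TPM in treated livers and passed in neither comparison (adjusted p = 0.0616 and 0.112). Ccnd1 was at 7.80 ± 2.59 TPM untreated and 6.49 ± 2.09 TPM treated (adjusted p = 0.695).

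Triglyceride synthesis and lipid droplet genes passed as a list (camera adjusted p = 0.0258; adjusted p = 0.524 with an estimated correlation), but their median of -0.01 and mean of 0.20 over 25 members differ in sign and 11 members lay above 0. Plin2 was the member called over all genes, with 3 higher and 1 lower adjusted over the list alone. Dgat1 (14.6 ± 0.157 and 13.5 ± 0.742 TPM, adjusted p = 0.623) and Dgat2 (143 ± 2.27 and 137 ± 11.6 TPM, adjusted p = 0.811), which encode the enzymes of the last step of triglyceride synthesis, did not pass. The list call was lost without aged untreated replicate 2 (0.15) or treated replicate 1 (0.111), with no filter (0.0803), with quantile normalization (0.0776), and with genes of 1 TPM in 6 libraries (0.058) or 5 TPM in 3 (0.115). Over all alternatives its median ranged from -0.06 with no filter to 0.16 without aged untreated replicate 3, with 0.09 for median-of-ratios scaling and 0.12 for array weights. The call of Plin2 was lost without treated replicate 2 (0.0671) or 3 (0.0527). Fatty acid oxidation genes did not pass as a list (median -0.05, 31 members, camera adjusted p = 0.137), while 3 members rose and none fell, also adjusted over the list alone. These were Angptl4, Ppara (11.1 ± 2.29 to 20.7 ± 1.43 TPM, limma adjusted p = 0.0158) and Cpt1a, the carnitine transferase that admits fatty acids to mitochondria (32.8 ± 1.89 to 50.5 ± 2.51 TPM, 0.0158). Cholesterol synthesis genes were higher as a list (median 0.11, 25 members, camera adjusted p = 0.000389; adjusted p = 0.569 with an estimated correlation), with Sqle called (23.3 ± 0.816 to 37.2 ± 7.40 TPM) and 2 higher adjusted over the list alone. Without treated replicate 1 that list had an adjusted p of 0.101 and a median of 0.03. The cholesterol median was -0.0012, 0.05 or 0.27 without aged untreated replicate 1, 2 or 3, 0.19 without treated replicate 3, 0.21 with median-of-ratios scaling and 0.23 with array weights. De novo lipogenesis genes did not pass (camera adjusted p = 0.134). In that list Srebf1, their transcription factor, was at 40.8 ± 20.0 and 12.8 ± 3.41 TPM (adjusted p = 0.0529) and Elovl6 at 7.21 ± 1.18 and 15.2 ± 1.83 TPM (0.0513).

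Among C/EBP factors and their chromatin partners, Cebpb (chromosome 2, 167688915 to 167690418) rose from 81.2 ± 9.15 to 159 ± 27.3 TPM (log2 fold change 0.96 ± 0.14, limma adjusted p = 0.0156). Without treated replicate 3 its adjusted p was 0.0589. Cebpa was at 154 ± 10.8 and 130 ± 1.33 TPM (adjusted p = 0.244), Ep300 at 1.67 ± 0.143 and 1.83 ± 0.0796 TPM (0.745) and Hdac1 at 11.7 ± 1.40 and 8.24 ± 0.361 TPM (0.0583). The list of 16 members did not pass (camera adjusted p = 0.274), with 1 member higher and 1 lower adjusted over the list alone.

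Acute phase genes were higher in treated than in untreated aged livers as a list. The median of the 28 members was 0.45 and 26 lay above 0 (camera adjusted p = 2.73e-10; adjusted p = 0.50 with an estimated correlation), with none called over all genes and 1 higher adjusted over the list alone. The acute phase median was 0.87 without aged untreated replicate 1, 0.20 without aged untreated replicate 3 and 0.21 with array weights. Saa1 read 3099, 7204 and 2730 TPM in treated replicates 1, 2 and 3, against 6008, 222 and 123 TPM in the untreated aged replicates. Neutrophil genes were higher as a list (median 1.13, 5 members, camera adjusted p = 0.000389; adjusted p = 0.50 with an estimated correlation), with none called over all genes and 3 adjusted over the list alone. With no filter the neutrophil list did not pass (0.157, median 0.06), and its median was 0.71 without aged untreated replicate 3 and 0.72 with array weights. Relative to the mean of the 9 libraries it stood at 1.13, -0.15 and -0.50 in aged untreated replicates 1, 2 and 3 and at 0.87, 1.39 and 0.96 in the treated ones. The list of inflammatory cytokines and senescence-associated secretion, called the cytokine list here, passed as well (median 0.10, 16 members, camera adjusted p = 0.00146; adjusted p = 0.50 with an estimated correlation), with Cxcl1 the member called and 2 higher adjusted over the list alone. The cytokine median was 0.28, 0.02 or 0.19 without aged untreated replicate 1, 2 or 3 and 0.22 or 0.03 without treated replicate 2 or 3. It was 0.52 with genes of 5 TPM or more in at least 3 libraries, 0.28 with genes of 1 TPM in 6, 0.19 with quantile normalization and 0.18 with median-of-ratios scaling. On the same scale per library, aged untreated replicate 1 (0.27) lay above all 3 treated libraries (0.20, 0.05 and 0.22). The call of Cxcl1 was lost without aged untreated replicate 2 (0.0582) and without treated replicate 2 (0.0716) or 3 (0.062). Genes of endoplasmic reticulum stress were higher as a list (median 0.49, 22 members, camera adjusted p = 7.95e-08; adjusted p = 0.50 with an estimated correlation). Chac1 rose from 0.879 ± 0.251 to 3.83 ± 0.728 TPM, while Atf4, the transcription factor upstream of it, fell from 92.8 ± 5.41 to 66.0 ± 4.84 TPM, and 5 members were higher and 1 lower adjusted over the list alone. The endoplasmic reticulum list stood at 0.40, -0.37 and -0.38 in aged untreated replicates 1, 2 and 3 and at 0.24, 0.63 and 0.32 in the treated ones, so aged untreated replicate 1 lay above treated replicates 1 and 3, and its median change was 0.31 with array weights. Immediate early and heat shock genes had a median of 0.39 over 18 members (camera adjusted p = 0.00794; adjusted p = 0.50 with an estimated correlation), with Junb higher, Klf2 lower, and 4 higher and 1 lower adjusted over the list alone. That list was not called with median-of-ratios scaling (adjusted p = 0.0556) or quantile normalization (0.0603). Its median was -0.03 without aged untreated replicate 3, 0.20 without treated replicate 2, 0.06 with no filter and 0.03 with array weights.

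Circadian clock genes were higher in treated livers as a list (median 0.55, 17 members, camera adjusted p = 0.000389; adjusted p = 0.50 with an estimated correlation), with Per1 higher (2.28 ± 0.618 to 5.02 ± 1.24 TPM), Cry1 lower (5.04 ± 0.858 to 1.91 ± 0.688 TPM), and 5 higher and 2 lower adjusted over the list alone. Relative to the mean of the 9 libraries the clock list stood at -0.03, -0.71 and 0.23 in aged untreated replicates 1, 2 and 3 and at -0.05, 0.75 and 0.38 in the treated ones, so aged untreated replicates 1 and 3 lay above treated replicate 1. The clock output gene Dbp read 0.645, 0.576 and 14.3 TPM in aged untreated replicates 1, 2 and 3 and 6.99, 27.7 and 21.9 TPM in the treated ones. In young replicates 1, 2 and 3 it read 14.0, 14.8 and 6.51 TPM. The list mixes clock genes of opposite phase, so its median does not give a direction of the clock. Without collection times, a difference in phase cannot be told apart from an effect of age or drug on clock genes such as Cry1, Per1 and Ccrn4l. Female-biased liver genes passed (median 0.27, 9 members, none called and 0 adjusted over the list alone; camera adjusted p = 0.0374, and adjusted p = 0.50 with an estimated correlation). That call was lost without aged untreated replicate 1 (0.248) or 3 (0.103), without treated replicate 1 (0.101), with median-of-ratios scaling (0.107) or quantile normalization (0.0776), with no filter (0.0731, median 0.03) and with a pseudocount of 1 (0.0511). The median was 0.43 with a pseudocount of 0.1, 0.42 with array weights and 0.43 with genes of 1 TPM in 6 libraries. Periportal genes were lower (median -0.24, 20 members, camera adjusted p = 0.0258; adjusted p = 0.50 with an estimated correlation), with Cdh1, the epithelial cadherin (5.6 ± 0.219 to 2.86 ± 0.924 TPM), and Igfbp2 (576 ± 24.9 to 396 ± 61.3 TPM) called and 5 lower adjusted over the list alone. Without aged untreated replicate 3 or treated replicate 2 that list had an adjusted p of 0.0706 or 0.0686, and the median was -0.15 without treated replicate 2 and -0.14 with median-of-ratios scaling.

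**Figure D3:**
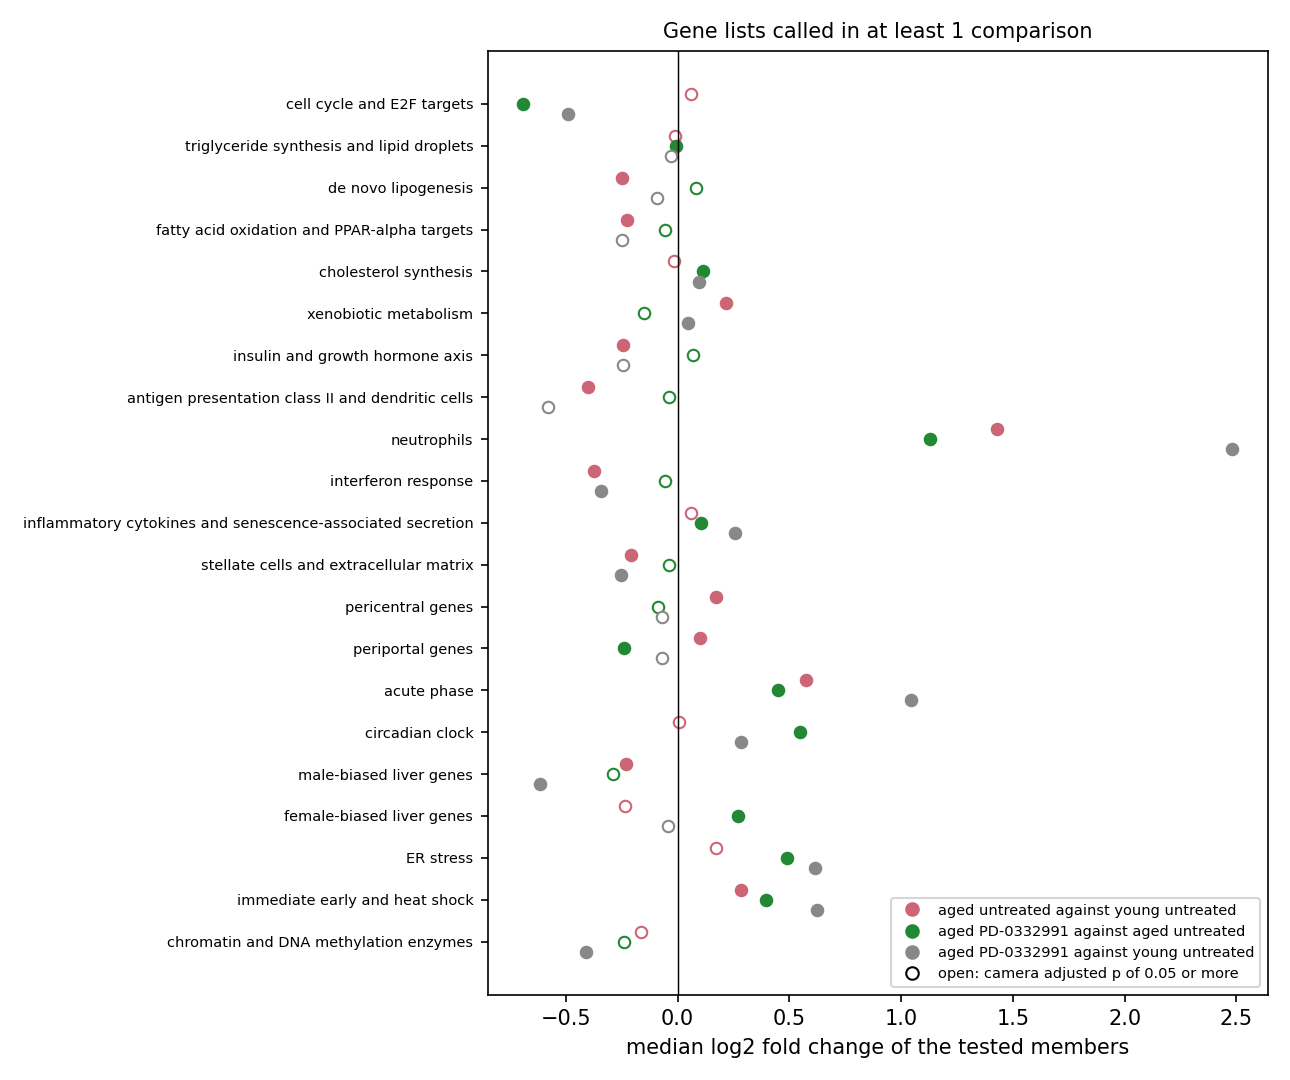
Median log2 fold change of the tested members of each gene list called in at least 1 comparison (filled: camera adjusted p under 0.05; open: not past it). The neutrophil list has medians of 1.43, 1.13 and 2.48 in the age, drug and treated against young comparisons, and the cell cycle list 0.06, -0.69 and -0.49.

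**Figure D4:**
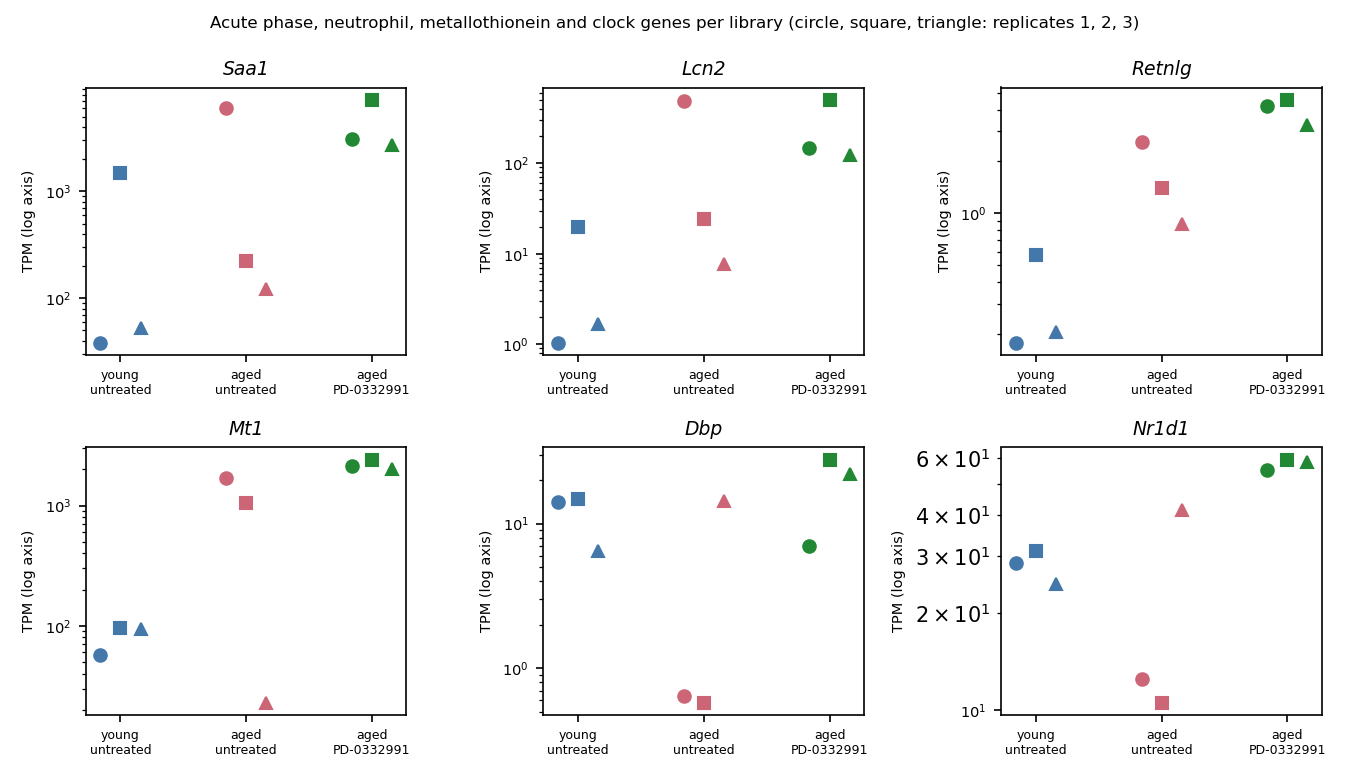
TPM per library on a log axis for Saa1, Lcn2, Retnlg, Mt1, Dbp and Nr1d1, by group (circle, square and triangle for replicates 1, 2 and 3). Aged untreated replicate 1 had 6008 TPM of Saa1 and aged untreated replicate 3 had 22.9 TPM of Mt1, against 1706 and 1057 TPM in replicates 1 and 2.

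The third comparison set treated aged livers against young untreated ones. Cxcl1 rose from 3.26 ± 0.684 to 165 ± 19.5 TPM (log2 fold change 5.47 ± 0.42, limma adjusted p = 0.00109), and Ccrn4l from 4.17 ± 2.19 to 37.9 ± 4.64 TPM (3.13 ± 0.35, 0.00329). Hhex fell from 89.5 ± 15.3 to 15.7 ± 4.97 TPM (log2 fold change -2.50 ± 0.23, limma adjusted p = 0.00109) and Cdh1 from 9.92 ± 0.994 to 2.86 ± 0.924 TPM (-1.66 ± 0.17, 0.00109). The other genes chosen by size under the same limits were Tifa (log2 fold change 3.67), C4a (3.35) and S100a9 (2.92), all higher, and Clec2h (-2.82), Cyp7a1 (-2.60) and Gbp11 (-1.85), all lower. In all, 699 genes were called, 263 higher and 436 lower, and 177 changed by at least 1 on the log2 scale. The split was 359 higher and 250 lower with median-of-ratios scaling and 308 and 310 with quantile normalization. An unadjusted p under 0.05 was reached by 2524 genes (508 by chance on average, 417 in the highest other split), and 33.9% of genes had no overlap between the groups (10% by chance). The count was 218, 381 and 257 without young replicate 1, 2 or 3, and 475, 153 and 252 without treated replicate 1, 2 or 3. Of the 96 named genes called here, 26 stayed past the threshold without any 1 library, among them Cxcl1, Ccrn4l, Hhex, Cdh1 and Gbp11. The other 70 kept their direction but were no longer called in at least 1 such fit, 66 of them without treated replicate 2, 52 without treated replicate 3, 50 without young replicate 1, 46 without young replicate 3, 35 without young replicate 2 and 25 without treated replicate 1. Their adjusted p then lay between 0.0503 and 0.152.

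Inflammatory gene groups were higher in treated than in young livers. Of 28 acute phase genes 7 rose and none fell (19 and 0 adjusted over the list alone), all 28 lay above 0 and the median was 1.04 (camera adjusted p = 1.16e-20; adjusted p = 0.422 with an estimated correlation). Socs3, an inhibitor of cytokine signalling, rose from 3.92 ± 1.33 to 18.2 ± 2.84 TPM and Saa4 from 83.2 ± 11.9 to 284 ± 29.4 TPM. Of the 5 tested neutrophil genes, out of 15 listed, 3 rose, Retnlg, S100a8 and S100a9, and 5 adjusted over the list alone. Their median was 2.48 (camera adjusted p = 3.2e-08, and adjusted p = 0.255 with an estimated correlation), and 0.39 with no filter. Retnlg read 0.178, 0.576 and 0.204 TPM in young replicates 1, 2 and 3, below the 1 TPM of the filter. Among the 16 members of the cytokine list Cxcl1, Icam1, Gdf15 and Ccl2 rose and none fell (4 and 1 adjusted over the list alone; median 0.25, camera adjusted p = 0.00424, and adjusted p = 0.422 with an estimated correlation), and the median was 0.15 without young replicate 1, 0.40 with quantile normalization and 1.44 with genes of 5 TPM or more in at least 3 libraries. Immediate early and heat shock genes had 5 of 18 members higher and 1, Klf2, lower (7 and 2 adjusted over the list alone; median 0.62, camera adjusted p = 6.74e-05, and adjusted p = 0.0986 with an estimated correlation), and the median was 0.26 with no filter. Endoplasmic reticulum stress genes had 2 of 22 members higher, Dnajb9 and Manf, and Atf4 lower (8 and 1 adjusted over the list alone; median 0.62, camera adjusted p = 1.5e-10, and adjusted p = 0.422 with an estimated correlation).

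Lists lower in treated than in young livers were the male-biased, cell cycle, interferon, chromatin enzyme and extracellular matrix genes. Of 24 male-biased genes 9 fell and 2 rose (12 and 2 adjusted over the list alone; median -0.62, camera adjusted p = 0.000426, and adjusted p = 0.58 with an estimated correlation). Among them Hsd3b2 fell from 23.1 ± 3.74 to 8.04 ± 2.03 TPM and Cyp2d9 from 909 ± 70.7 to 570 ± 30.4 TPM, while Susd4 rose. Of 21 cell cycle genes 5 fell, Mcm10, Cdk2, Aurka and E2f8 among them (7 adjusted over the list alone; median -0.49, camera adjusted p = 0.0014, and adjusted p = 0.58 with an estimated correlation), and the median was -0.31 with genes of 5 TPM or more in at least 3 libraries. Mcm10 was at 31.6 ± 2.42 TPM in young livers, while no other cell cycle member averaged above 20.9 TPM there. Of 32 interferon genes 4 fell and 2 rose (12 and 2 adjusted over the list alone; median -0.34, camera adjusted p = 0.0043, and adjusted p = 0.58 with an estimated correlation). Chromatin and DNA methylation enzymes had Kat2b lower and 5 lower adjusted over the list alone (median -0.41 over 14 members, camera adjusted p = 0.00527, and adjusted p = 0.538 with an estimated correlation), and the median was -0.26 with quantile normalization. Extracellular matrix genes had Col3a1, Sparc and Col1a2 lower, 3 also adjusted over the list alone (median -0.25, camera adjusted p = 0.0445, and adjusted p = 0.66 with an estimated correlation). That last call was lost without young replicate 1 (0.183) and without treated replicate 2 (0.245, median -0.16) or 3 (0.116). It was also lost with the replicate number as a block (0.0513), with rescaled values (0.0509) and with genes of 5 TPM or more in at least 3 libraries (0.115), and the median was -0.16 with median-of-ratios scaling.

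Other lists higher in treated than in young livers were those of cholesterol synthesis, xenobiotic metabolism and the clock, each with a camera adjusted p of 0.00527. Cholesterol synthesis, with 25 members, had Sqle among those higher and 3 higher adjusted over the list alone (median 0.10; adjusted p = 0.66 with an estimated correlation), and without treated replicate 1 its adjusted p was 0.208 and its median -0.02. The median was 0.15 or 0.15 without treated replicate 2 or 3 and 0.20 with median-of-ratios scaling. Xenobiotic metabolism had 4 of 29 members higher, Cyp2c37, Cyp3a13 and Por among them, and Ugt2b5 lower (5 and 1 adjusted over the list alone; median 0.05; adjusted p = 0.58 with an estimated correlation). With quantile normalization that list had an adjusted p of 0.324. Its median was 0.08, -0.06 or 0.15 without young replicate 1, 2 or 3, 0.12 or 0.03 without treated replicate 2 or 3, 0.03 with rescaled values and 0.15 with median-of-ratios scaling. The clock list had Nfil3 and Per1 higher of 17 members, 2 also adjusted over the list alone (median 0.28; adjusted p = 0.58 with an estimated correlation), and without treated replicate 2 its adjusted p was 0.056 and its median 0.10. That median was 0.18 without young replicate 3, 0.53 without treated replicate 1 and 0.18 with array weights. Of the lipid genes, Plin2 did not pass (304 ± 17.5 and 417 ± 64.1 TPM, adjusted p = 0.0896), while Mogat1 rose from 0.532 ± 0.0953 to 1.56 ± 0.255 TPM and Srebf1 fell from 33.2 ± 5.21 to 12.8 ± 3.41 TPM. Cebpb rose from 81.0 ± 8.53 to 159 ± 27.3 TPM and Hdac1 fell from 12.2 ± 0.672 to 8.24 ± 0.361 TPM. Per library, the list medians of the groups compared overlapped for 6 of the 13 lists called with age, those of xenobiotic metabolism, class II, extracellular matrix, pericentral, acute phase and male-biased genes. With the drug they overlapped for 8 of 11, all but the cell cycle, periportal and immediate early lists, and for treated against young livers for 5 of 13, those of cholesterol synthesis, xenobiotic metabolism, cytokine, extracellular matrix and clock genes.

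How the drug effect related to the age effect was measured over the 10161 tested genes, which are not independent replicates. Pearson's r was -0.179 and Spearman's rho -0.251, and 57.4% of genes had opposite signs. The aged untreated libraries enter both effects with opposite sign, and simulations with no change in any group gave a mean r of -0.487 (95% of 1000 draws between -0.712 and -0.176), rho of -0.449 and 66.0% opposite signs. The covariance was -0.0193, against a simulated mean of -0.0246 (95% between -0.0489 and -0.0084), a difference of 0.00531. These draws pooled the residuals of all 3 groups, while only the noise of the aged untreated libraries is shared. Those libraries were the most spread (median SD over genes 0.186, against 0.147 in young and 0.144 in treated livers). The draws may therefore understate the shared noise, and a covariance within their range does not show that the effects are unrelated. Among the 3967 genes with a mean of 10 TPM or more, r was 0.0194 and the covariance 0.00197 (simulated means -0.478 and -0.023). Both lay above the range of 95% of the simulated draws, -0.781 to -0.0458 for r and -0.0514 to -0.00169 for the covariance. The draws hold no effects, and real effects of age or drug would move r toward 0 even if unrelated. An r above the range therefore does not show how the effects relate. In a test chosen after the data were seen, the aged untreated libraries were divided into 1 and 2, one part for each effect, so that none entered both. Over the 6 ways to do this r averaged 0.0987 (from -0.159 to 0.305) and the covariance 0.0182 (from -0.0186 to 0.0556), with 5 of the 6 above 0, and the averages were 0.224 and 0.0393 at 10 TPM or more. The value below 0 came from aged untreated replicates 2 and 3 for the age effect and replicate 1 for the drug effect.

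Among the called genes, 8 were higher with age and lower with the drug, among them Cry1, Igfbp2, Adam11 and Ppp1r3c, and 8 were lower with age and higher with the drug, among them Ppara, Hykk and Wsb1. Independent lists would share 0.552 and 0.281 genes. Simulations without effects call almost no genes at this threshold, so their mean of 0.02 shared genes in each case gives no usable comparison. Hhex was lower in both comparisons, and no gene was higher in both (0.385 and 0.403 for independent lists). At an unadjusted p under 0.05, 259 genes were higher with age and lower with the drug, against 51.7 on average in the simulations and 102 for independent lists, and 120 were lower with age and higher with the drug, against 52.3 and 37.4. In the same direction there were 40 higher in both (0.68 and 38.1) and 61 lower in both (0.77 and 100). These simulations leave out the effects and the correlation between genes, and the independent lists leave out the shared libraries. The overlap was not measured with divided libraries, because 3 cannot give 2 parts of at least 2 libraries each, so part of the excess may come from the shared libraries. Another clock phase in aged untreated libraries would also make the effects opposite, in clock genes such as Cry1. Dbp read 0.645 and 0.576 TPM in aged untreated replicates 1 and 2, against 6.51 to 27.7 TPM in young and treated libraries. How much of the overlap comes from this was not tested. Most genes called with age kept their direction in treated against young livers, 64 of 66 higher and 42 of 46 lower ones, with 39 and 24 still called. The median log2 fold change was 0.92 with age and 0.68 in treated against young livers for the higher genes. It was -0.86 and -0.58 for the lower ones. Both comparisons use the young libraries, which favours the same sign. The genes were chosen by their change with age in these same libraries, which enlarges the age medians. A smaller median in treated against young livers can follow from that choice alone, so it does not measure a return toward young levels.

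**Figure D5:**
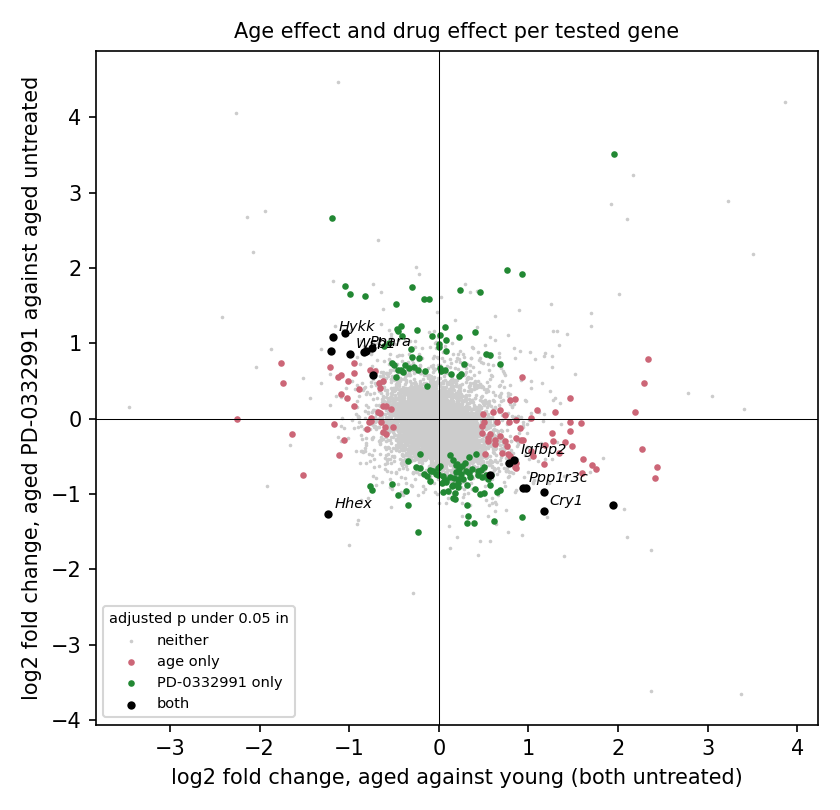
Log2 fold change with age (x axis, aged against young, both untreated) and with PD-0332991 (y axis, treated against untreated aged livers) for each of the 10161 tested genes, coloured by the comparison in which the gene was called. Of the genes called in both, 16 lie in the quadrants of opposite sign and Hhex lies below 0 on both axes.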

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

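The rescaled, median-of-ratios and quantile scalings, the array weights, the filters of 1 TPM in 6 libraries and 5 TPM in 3, and the division of the aged untreated libraries were chosen after the data were seen; the other alternatives were planned. Planned tests that need counts (DESeq2, voom, edgeR factors, a CPM filter) were not run because the tables hold TPM, and without counts the depth of each library and its counting noise stay unknown. Of 178 called results of named genes 34 passed in every setting that was applied to them, and no called gene changed sign. For single genes the fits without 1 library covered only the libraries of the comparison. The fold change threshold, the set tests and the settings for the relation of effects were not among their settings. The camera direction of no called list turned, but the median changed sign in some setting for 5 of 37 called list results and moved by over 1.5 times, or changed sign, for 29. The counts below are given as higher, lower and all genes called, in the order age, drug, and treated against young. The main counts were 66, 46 and 112 with age, 62, 85 and 147 with the drug, and 263, 436 and 699 for treated against young livers. Leaving out 1 library gave 12 to 378, 4 to 318 and 16 to 696 with age, 5 to 163, 2 to 229 and 7 to 392 with the drug, and 74 to 188, 79 to 287 and 153 to 475 for the last. With no filter they were 40, 22 and 62 with age and 16, 13 and 29 with the drug. With an adjusted p under 0.01, a stricter threshold, they were 21, 5 and 26, then 3, 0 and 3, then 69, 61 and 130, and 8 lists instead of 13 were called with age. With an absolute log2 fold change of 1 or more, also stricter, they were 29, 18 and 47, then 27, 14 and 41, then 100, 77 and 177. Fitting only the 6 libraries compared gave 32, 17 and 49, then 15, 10 and 25, then 431, 851 and 1282. The replicate number as a block gave 31, 29 and 60 with the drug and 289 lower for treated against young, although libraries of the same number did not pair (r of residuals from -0.22 to 0.166, with 4 of 9 libraries closest to their own number). Array weights gave 267, 223 and 490, then 116, 155 and 271, then 431, 923 and 1354. Median-of-ratios factors gave 109 higher and 56 lower with the drug and 250 lower for treated against young, and quantile normalization gave 56 lower with the drug. With an estimated correlation 0 lists were called in each comparison, against 13, 11 and 13, and fry called 0 with age and 0 with the drug. With 5 TPM in 3 libraries 7 lists were called with the drug. Between the age and drug effects, r was -0.179 and ranged from -0.377 to -0.137 without 1 library. It was -0.26 with no filter and 0.0194 at 10 TPM or more, a reversed sign. The covariance of -0.0193 ranged from -0.0531 to -0.016, and was -0.0322 with a pseudocount of 0.1 and 0.00197, also reversed, at 10 TPM or more. With the aged untreated libraries divided between the effects both were reversed, with a mean r of 0.0987 and a mean covariance of 0.0182. The cause of these shifts was not tested, apart from the stricter thresholds.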

Other observations

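All tests of explanations below were chosen after the result they weigh had been seen, except the test of a mislabelled library. Several gene groups did not pass as lists but held called members. Among 21 bile acid genes, Fgfr4, the receptor through which bile acid synthesis is repressed, fell with the drug from 16.3 ± 0.985 to 9.31 ± 0.585 TPM (limma adjusted p = 0.016), with 4 members lower adjusted over the list alone. Cyp7a1, the first enzyme of bile acid synthesis, was at 21.0 ± 8.58 and 3.64 ± 0.793 TPM there (adjusted p = 0.0504). Against young livers it fell in treated ones from 27.4 ± 17.4 TPM (0.0155), as did the sterol exporter genes Abcg5 (30.4 ± 4.63 to 15.1 ± 1.02 TPM, 0.00424) and Abcg8 (0.0128), while Cyp7b1 rose from 125 ± 46 to 253 ± 20.3 TPM (0.019). The glycogen-targeting gene Ppp1r3c rose with age from 10.9 ± 3.15 to 20.8 ± 2.71 TPM (0.0399) and fell with the drug to 10.7 ± 0.796 TPM (0.0342).

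Macrophage and Kupffer cell genes did not pass as a list, by a small margin, for treated against young livers (median log2 fold change -0.51 over 20 members, camera adjusted p = 0.0503). Of them 5 fell and none rose (9 and 1 adjusted over the list alone), with Clec4f going from 30.7 ± 6.36 to 18.1 ± 0.529 TPM and Csf1r from 7.58 ± 2.23 to 3.96 ± 0.664 TPM. In the NRF2 and metallothionein list (18 members, camera adjusted p = 0.99) 2 members rose and 4 fell in the same comparison (4 and 6 adjusted over the list alone). The heme oxygenase gene Hmox1 rose from 7.68 ± 2.13 to 17.5 ± 1.46 TPM (0.0116), and Gclc, needed to make glutathione, fell from 96.3 ± 20.5 to 48.9 ± 2.99 TPM (0.0177). Nuclear genes of oxidative phosphorylation had no called member among 51 in any comparison (camera adjusted p = 0.742 with age, 0.0983 with the drug and 0.292 for treated against young).

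Aged untreated replicate 3 stood apart from replicates 1 and 2, and the number of genes called with age rose from 112 to 696 without it. Another phase of the clock at collection, in this library or in replicates 1 and 2, may account for part of this. Its 6 clock output genes differed from its 4 genes of the opposite phase by 1.64 in their deviation from group mates, against at most 0.88 in any other library. The odd library of 3 deviates most from its mates by construction, so this does not show which libraries were shifted. In Dbp and Nr1d1 replicates 1 and 2 stood apart from all other libraries, and replicate 3 did not. Dbp read 0.645 and 0.576 TPM in replicates 1 and 2, 14.3 TPM in replicate 3 and 6.51 to 27.7 TPM in young and treated libraries. For Nr1d1 these were 12.5 and 10.6, 41.4, and 24.6 to 59.3 TPM. Of the 696 genes, 32.2% lay nearer to the aged than to the young mean in this library. For the 16 to 64 genes called without each of the other 5 libraries, 84% to 100% lay nearer to their own group. Of the 392 genes called with the drug without replicate 3, 48.2% lay nearer in it to the untreated aged than to the treated mean. Its r over genes was 0.976 to 0.981 with the young libraries and 0.965 to 0.9755 with the treated ones. With aged untreated replicates 1 and 2 it was 0.972 and 0.970. These values do not settle whether replicate 3 is mislabelled. A real difference between mice stays possible, and the files give no collection times.

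Acute phase and neutrophil genes were higher in the treated livers as lists, with 0 of 28 and 0 of 5 members called over all genes and an adjusted p = 0.50 for each list with an estimated correlation. The neutrophil list was not called with no filter either (0.157). A state that also occurs without the drug may contribute, because the acute phase median of aged untreated replicate 1 lay 0.25 above the lowest treated one. The list call cannot decide on scaling between libraries, because camera sets members against all other genes and a factor per library moves both almost alike. With median-of-ratios factors the acute phase list median was 0.55 (camera adjusted p = 1.86e-07; over all alternatives from 1.74e-22 without aged untreated replicate 1 to 0.50 with an estimated correlation). These factors moved the median of all genes from -0.09 to -0.0023, a shift smaller than the list median of 0.45 on the main scale. A lower share of hepatocytes would raise markers of other resident cells. This was weighed for the neutrophil list alone, not for the acute phase genes, which the liver itself secretes. The upper quartile of 68 markers of macrophages, stellate cells and endothelium was -0.0053, while the lower quartile of neutrophil markers was 0.59. The neutrophil markers thus did not rise together with these. The 68 markers may themselves change with the drug (median -0.28 for macrophage genes), so a lower share is not excluded. An effect of the drug on inflammation remains open.

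More genes were lower than higher in the treated livers, with 42.2% of called genes higher. This balance was not firm in settings that leave the scaling as it was. The share was 41.5% with a pseudocount of 0.1 and 42.8% with array weights. It was 55.2% with no filter, 51.7% with the replicate number as a block and 60% with the 6 compared libraries alone. At an absolute log2 fold change of 1 or more it was 65.9%. The share was 66.1% with median-of-ratios factors, but these center the genes of each library and so largely set the balance, and it was 43.7% with the listed values rescaled to the same total. The median of all genes was -0.09 on the main scale. Scaling between libraries and a real shift in the total RNA of treated livers cannot be told apart with TPM.

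Splitting the 6 libraries of a comparison into 3 and 3 in other ways gives 10 splits, too few for a share under 0.05. The real grouping, 1 of 10 in each comparison, was alone in calling as many genes. It called 112 genes with age against 28 for the highest other split, 147 with the drug against 0, and 699 for treated against young against 0. At an unadjusted limma p under 0.05 these were 1523 against 1434, 1854 against 965 and 2524 against 417 genes. Each other split mixes the real groups, so a real difference widens the spread within its parts and can lower its count. The 417 genes lay below the 508 that chance gives on average. The other splits therefore do not show the count without an effect.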
